A study of Mus musculus with 24 samples.

How the data were processed

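The study measured RNA in microglia, the resident macrophages of the brain, in 24 libraries in 4 groups of 6. Per the labels' protocols, microglia were sorted from mouse brain by fluorescence-activated cell sorting into lysis buffer, total RNA was extracted, and complementary DNA was made and amplified by Smart-seq2 before library construction. The deposited table holds estimated counts per Entrez gene identifier, not scaled between libraries; 76.8% of the genes with values were whole numbers in every library. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The table had 22064 gene identifiers, of which 6186 were blank in every library and were left out. The other 15878 had a value in every library. A gene symbol was found for 22002 identifiers in the RefSeq gene table of assembly GRCm38.p6, used for names only; 62 identifiers found none. Mitochondrially encoded genes had no values in the table, so their list and their share of counts are not analysed here.

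Library totals were 24278000 to 28892000 counts, and 8515 to 10794 genes had a count in a library. Depth was therefore similar throughout, but 52% of the tested genes had no count in at least 1 library, which goes with small amounts of input RNA. The pairwise Pearson correlation of libraries, across genes, was 0.648 to 0.79, and no pair of libraries was alike enough to be a duplicate. The labels do not say that the 6 samples of a group came from separate mice and name no batch, so the p-values measure the spread between these samples, which may in part be technical. Amplified reads without molecular identifiers are not independent molecules.

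Values were rounded to whole counts and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (a minimum of 10 counts), which left 10219, and libraries were scaled by TMM, with factors from 0.936 to 1.17. Dispersions were estimated over all 24 libraries in 1 fit with 4 group means, and each comparison was a robust quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were BCAS against Sham, each exosome group against BCAS, and WD-Exos against ND-Exos. Levels are CPM, counts scaled to a common library total, on the TMM scale, as mean ± SD with n = 6; log2 fold changes are given with their standard error (SE). The biological coefficient of variation had a common value of 1.45 over all tested genes and a median of 0.329 over the 1423 genes with a mean above 100 CPM, for which the median SE of a log2 fold change was 0.241. Over all genes the median SE was 1.1.

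Gene lists fixed before the data were examined, 36 in number, covered microglial states, inflammation, metabolism, stress responses and markers of other brain and blood cell types. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, and again with an estimated correlation and with fry; the score of a list in a library is the mean log2(CPM + 1) of its tested members. The other 10 lists had too few tested members: mitochondrially encoded genes and markers of oligodendrocyte precursors, neurons, mural cells, monocytes, neutrophils, T and NK cells, B cells, erythroid cells and ependymal cells. All marker lists, depth, detected genes and ribosomal share were also compared as 17 measures per library by exact two-sided permutation tests, 68 tests in 1 family. With 6 against 6 libraries the smallest p such a test can give is 0.00216.

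The tests, the lists and the rule for named genes were fixed before the data were examined. In each comparison the rule took up to 8 genes that rose and 8 that fell among genes past the threshold with an established symbol and a count in every library of the higher group, then up to 3 past the threshold from each list. Where a list passed camera but fewer than 2 members did, its 2 members with the smallest p were named. Where fewer than 4 genes passed, the 3 higher and 3 lower genes with the smallest p were named as not past it. P2ry12, Tmem119 and Cx3cr1 were given as levels throughout. Some genes that these rules picked are not reported here. Gm20594 falls outside the rule and was chosen after its values were seen. Nfe2l2 was added in the same way.

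The procedure was tested on simulated data for BCAS against Sham, in 3 simulations of all 10219 genes with the real means, library sizes and dispersions and 200 genes above 100 CPM changed. It recovered 45% of the genes changed 2-fold and 95.3% of those changed 4-fold, with 4.67 unchanged genes called per simulation. Alternatives were size factors of the DESeq2 type, no filter and stricter filters on low counts, the replicate number as a block, covariates, only the libraries of the 2 groups, voom with library weights, DESeq2 1.42.0, and leaving out each library in turn. Transcripts were aligned with blastn 2.17.0 to GENCODE release 21 for mouse (vM21), and figures were drawn with matplotlib 3.10.9.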

Results

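RNA was measured in microglia sorted from mouse brain on day 28. The 4 groups held 6 libraries each: sham-operated mice given saline (Sham), mice given the BCAS operation and saline (BCAS), and BCAS mice given exosomes of the kind the labels call ND-Exos or WD-Exos. BCAS is the usual short name of bilateral carotid artery stenosis, an operation that lowers blood flow to the forebrain and injures white matter. Exosomes, small vesicles that cells release, were injected into the tail vein at 100 µg every 3 days. The title of the series says that the exosomes came from foam cells, which are lipid-laden macrophages, and asks about metabolic defects in microglia. Library totals ranged from 24278000 to 28892000 counts. Microglial transcripts were abundant throughout. The fractalkine receptor Cx3cr1 stood at 3663 ± 319 CPM (SD, n = 6) in Sham, 4772 ± 964 in BCAS, 4645 ± 1180 with ND-Exos and 4808 ± 762 with WD-Exos. The homeostatic marker Tmem119 stood at 1630 ± 384, 1852 ± 678, 1462 ± 318 and 2245 ± 607 CPM in the same order. P2ry12, also homeostatic, stood at 3757 ± 512, 5346 ± 970, 6023 ± 1724 and 4756 ± 1373 CPM.

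The first comparison, BCAS against Sham, asks what the operation changed in microglia 28 days on. Transcripts of cytosolic ribosomal proteins, the protein part of the ribosome, fell as a group. All 81 tested members had a lower level in BCAS, with a median log2 fold change of -0.47. Of the 81, 67 passed when adjusted over the list alone (0 over all genes tested). Rplp1 stood at 958 ± 206 CPM in BCAS and 1545 ± 158 in Sham (log2 fold change -0.69, SE 0.15, n = 6, adjusted p = 0.166). Rps24 stood at 417 ± 123 and 709 ± 101 CPM (-0.77, SE 0.17, adjusted p = 0.166). Rps28, at 329 ± 82.1 and 555 ± 65.7 CPM, had the same adjusted p. Ribosomal proteins took 4.27 ± 0.76% of all counts in BCAS and 5.88 ± 0.53% in Sham (exact permutation p = 0.00866, adjusted p = 0.331 over 68 tests). The camera test of the list gave an adjusted p of 2e-42, and adjusted p = 0.257 with an estimated correlation. It was 0.0115 by fry, which asks whether the members move one way.

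Nuclear genes of oxidative phosphorylation also fell as a list (55 of 74 members lower, median log2 fold change -0.17, camera adjusted p = 0.00523; adjusted p = 0.447 with an estimated correlation). Its member Cox5a, a subunit of cytochrome c oxidase, stood at 65.3 ± 16.1 CPM in BCAS and 115 ± 18.5 in Sham (adjusted p = 0.376). Markers of border macrophages, which line vessels and meninges, fell (8 of 9 members lower, median -1.20, camera adjusted p = 0.0208; adjusted p = 0.342 with an estimated correlation). Among these, Cd163 stood at 1.41 ± 2.17 and 25.1 ± 20.1 CPM and Pf4 at 30.6 ± 27.7 and 94.6 ± 96.0 CPM in BCAS and Sham. The log2 fold change of Pf4 went from -1.63 to -1.05 without Sham replicate 1, and that of Cd163 from -4.15 to -4.98 without BCAS replicate 6. Over all border macrophage markers the summed CPM was 361 ± 184 in BCAS and 672 ± 565 in Sham (exact permutation p = 0.284, adjusted p = 0.643). The medians, 391 and 365, ran the other way, and Sham replicates 1 (1657) and 3 (1059) carried the higher mean. The summed CPM of mural cell markers was 0.075 ± 0.051 in BCAS and 207 ± 408 in Sham (exact permutation p = 0.0152). Of 14 neutrophil markers only 6 had values, and 2 passed the filter on counts. The summed CPM of the 6 was 433 ± 158 in BCAS and 248 ± 42.1 in Sham (exact permutation p = 0.0195), which rests on few genes. The mural and neutrophil sums both had an adjusted p of 0.331.

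The lists that rose in BCAS were homeostatic microglia, interferon response, inflammatory cytokines and NF-kB targets, immediate early and heat shock genes, and antigen presentation. Of 20 homeostatic genes 17 were higher (median 0.24, camera adjusted p = 0.000384; adjusted p = 0.34 with an estimated correlation). They were led by the purinergic receptors P2ry13 (1812 ± 622 against 1104 ± 285 CPM, adjusted p = 0.392) and P2ry12 (5346 ± 970 against 3757 ± 512 CPM, adjusted p = 0.441). Of 25 interferon response genes 22 were higher (median 0.81, camera adjusted p = 8.11e-05; adjusted p = 0.34 with an estimated correlation). Among them was Ifit3 (94.7 ± 76.7 against 29.5 ± 15.9 CPM, adjusted p = 0.441). Of 20 antigen presentation genes 13 were higher (median 0.16, camera adjusted p = 0.00933; adjusted p = 0.34 with an estimated correlation). Of the 20, 3 passed adjusted over the list alone (0 over all genes tested), including the class I heavy chains H2-D1 (4154 ± 1692 against 2429 ± 598 CPM) and H2-M3 (125 ± 61.4 against 50.4 ± 27.9 CPM), both with adjusted p = 0.376 over all genes. Of 19 inflammatory genes 15 were higher (median 1.14, camera adjusted p = 0.00252; adjusted p = 0.34 with an estimated correlation). Nfkbiz stood at 120 ± 169 CPM in BCAS and 1.63 ± 3.04 in Sham (log2 fold change 6.20, and 8.20 without Sham replicate 2). The score of the inflammatory list was 4.63 ± 1.25 in BCAS and 3.82 ± 0.60 in Sham (exact permutation p = 0.199, adjusted p = 0.433). BCAS replicates 1 (5.867) and 2 (6.299) lay above every Sham library, and replicates 5 (3.272) and 6 (3.374) were the lowest of BCAS. The same libraries were highest and lowest in the immediate early score. The cytokine Il6 stood at 3.10 ± 3.57 CPM in BCAS, in 3 of 6 libraries, and at no count in Sham. That is 164-fold higher than a floor of 3 counts over the Sham group, which is not a lower bound because amplified reads are not independent molecules. Of 22 immediate early and heat shock genes, which respond within minutes to stress and to handling of cells, 18 were higher (median 1.26, camera adjusted p = 0.006; adjusted p = 0.556 with an estimated correlation). Atf3 stood at 447 ± 721 against 32.5 ± 33.8 CPM and Egr1 at 1193 ± 1496 against 298 ± 210 CPM. Without BCAS replicate 2 the log2 fold change went from 3.78 to 2.37 for Atf3 and from 2.002 to 1.08 for Egr1. The score of this list was 6.15 ± 1.62 in BCAS and 5.66 ± 0.43 in Sham (exact permutation p = 0.5, adjusted p = 0.71). BCAS replicates 1 (7.462) and 2 (8.674) lay above every Sham library, whereas BCAS replicates 5 (4.618) and 6 (4.678) lay below every Sham library.

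In the lists above other than ribosomal proteins and antigen presentation, 0 members passed adjusted over the list alone or over all genes tested. No single gene passed the edgeR test in BCAS against Sham. Of 10219 genes tested, 617 had an unadjusted p under 0.05, where chance gives 511, and the smallest adjusted p was 0.131. DESeq2 called 593 and voom with library weights 9. Of the higher genes, Marcks had the smallest p (812 ± 202 against 453 ± 54.2 CPM, log2 fold change 0.84, SE 0.16, adjusted p = 0.131). Next came the inhibitory receptor Lair1 (914 ± 144 against 490 ± 72.0 CPM, 0.90, SE 0.18, adjusted p = 0.131) and the RNA-binding protein Qk (1173 ± 258 against 621 ± 99.7 CPM, 0.92, SE 0.19, adjusted p = 0.166). Every BCAS library was above every Sham library for Marcks and Lair1. Without BCAS replicate 2, 32 genes passed, Marcks, Lair1, Qk, Rplp1, Rps24 and Rps28 among them, and 5 lists. Immediate early genes (adjusted p = 0.625), NF-kB targets (0.0764) and border macrophage markers (0.28) no longer did. Border macrophage markers were also lost without Sham replicate 1 (0.208) or 3 (0.109), immediate early genes without BCAS replicate 1 (0.0841), and antigen presentation without Sham replicate 1 (0.0719), 4 (0.0757) or 6 (0.0518) or BCAS replicate 5 (0.215) or 6 (0.0677). The difference in interferon score, BCAS minus Sham, was 1.81 among replicate numbers 4 to 6 and -0.545 among numbers 1 to 3, where 3 against 3 libraries cannot go below an exact p of 0.1.

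ND-Exos against BCAS asks what exosomes of the ND kind changed in operated mice. Lgals3bp, a secreted glycoprotein that interferon induces, fell to 380 ± 113 CPM with ND-Exos from 1303 ± 526 CPM in BCAS (log2 fold change -1.78, SE 0.30, n = 6, adjusted p = 0.0115). In Sham, Lgals3bp stood at 606 ± 199 CPM. It did not pass in BCAS against Sham (log2 fold change 1.105, SE 0.29, adjusted p = 0.356, and 0.0413 without BCAS replicate 2). For Lgals3bp, every ND-Exos library was below every BCAS library. Interferon response genes fell with it: 20 of 25 were lower, with a median log2 fold change of -1.16 (camera adjusted p = 6.74e-09; adjusted p = 0.473 with an estimated correlation). In the list 4 passed adjusted over the list alone (0 over all genes tested). Ifi27l2a stood at 43.8 ± 27.8 CPM with ND-Exos and 174 ± 79.5 in BCAS (log2 fold change -1.99, SE 0.51, adjusted p = 0.577). Antigen presentation genes fell as well (16 of 20 lower, median -0.30, camera adjusted p = 0.00157; adjusted p = 0.473 with an estimated correlation). In the list 4 passed adjusted over the list alone (0 over all genes). H2-D1 stood at 2154 ± 279 and 4154 ± 1692 CPM and H2-K1 at 721 ± 149 and 1336 ± 717 CPM with ND-Exos and in BCAS, both with adjusted p = 0.577. Astrocyte and mural cell markers were higher with ND-Exos but did not pass. All 5 tested astrocyte markers were higher (camera adjusted p = 0.116), with a score of 3.41 ± 1.18 against 2.08 ± 0.55 (exact permutation p = 0.039, adjusted p = 0.732) and 5 of 6 ND-Exos libraries above every BCAS library. The summed CPM of all 13 astrocyte markers was 226 ± 67.1 against 164 ± 69.5 (exact permutation p = 0.149), and that of mural markers 5.62 ± 8.39 against 0.075 ± 0.051 (exact permutation p = 0.0368, adjusted p = 0.5). ND-Exos replicates 3 (15.6) and 5 (17.2) carried the mural mean, and the medians were 0.38 and 0.082 CPM. BCAS was the lowest group for mural markers, with 207 ± 408 CPM in Sham and 5.25 ± 8.45 with WD-Exos.

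The other gene past the threshold was Gm20594, which rose to 694 ± 138 CPM with ND-Exos from 300 ± 38.8 CPM in BCAS (log2 fold change 1.21, SE 0.17, adjusted p = 0.00109), with every ND-Exos library above every BCAS library. Its transcript resembles the mitochondrial 16S ribosomal RNA (88.5% identity over 435 aligned bases), so its counts are uncertain. Not past the threshold, with adjusted p from 0.492 to 0.577, were citrate synthase Cs (98.91 ± 28.95 against 196 ± 41.1 CPM) and the NADPH oxidase subunit Ncf1 (289 ± 130 against 541 ± 130 CPM), both lower with ND-Exos. The small Maf protein Mafg was higher (61.9 ± 30.1 against 12.01 ± 11.66 CPM, log2 fold change 2.36, and 3.00 without BCAS replicate 2). Eme2 (10.7 ± 7.68 CPM) and H4c9 (2.03 ± 1.60 CPM) had no count in BCAS and a count in all 6 ND-Exos libraries. These levels were 541-fold and 103-fold above a floor of 3 counts over the group. Amplified reads are not independent molecules, so these are not lower bounds of a change. The lowest ND-Exos library stood at 0.072 CPM for Eme2 and 0.036 CPM for H4c9. In Sham, Eme2 stood at 0.054 ± 0.13 CPM and H4c9 at 1.51 ± 1.42 CPM, so for H4c9 BCAS was the low group. In all, 457 genes had an unadjusted p under 0.05, where chance gives 511, and DESeq2 called 481. The call of Lgals3bp was lost in 4 of 12 fits that left out 1 library, which then called 1 gene: BCAS replicate 5 (adjusted p = 0.0599) and ND-Exos replicates 1 (0.0626), 2 (0.059) and 6 (0.0693). It was also lost with the number of detected genes as a covariate (adjusted p = 0.0741), with voom (0.33) and without the 3 libraries richest in oligodendrocyte markers (0.0953), each of which kept Gm20594. The interferon score difference was -0.374 among replicate numbers 1 to 3 and -1.5 among numbers 4 to 6. Leaving out BCAS replicate 2 raised the number of lists from 2 to 5, leaving out BCAS replicate 4 raised it to 4, and leaving out BCAS replicate 5 took the antigen presentation list to an adjusted p of 0.0996.

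**Figure D1:**
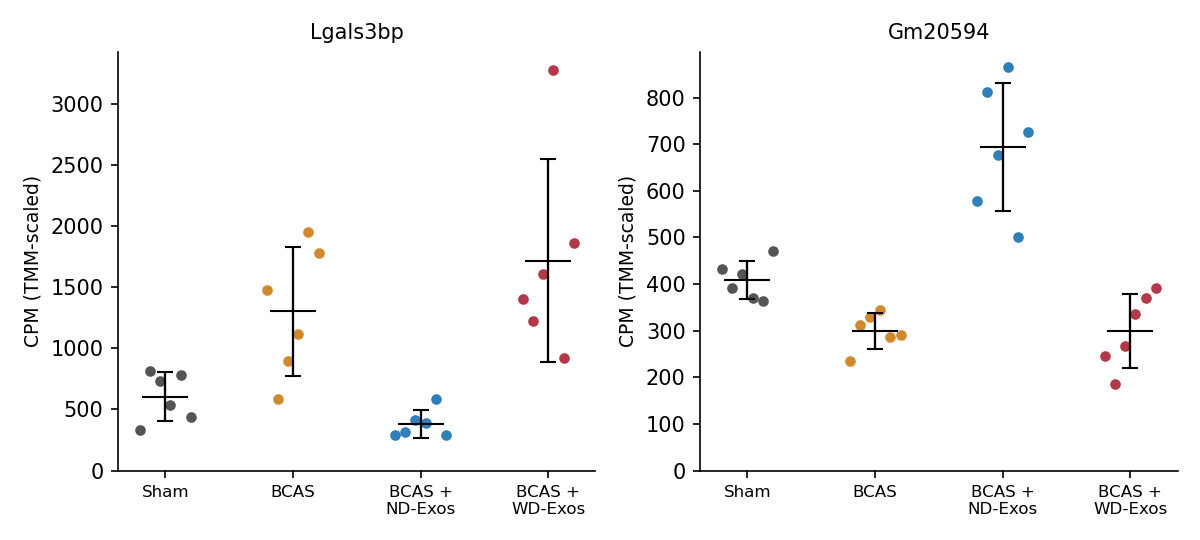
Levels of Lgals3bp (left) and Gm20594 (right) in CPM on the TMM scale, both axes from 0. Each point is 1 library, 6 per group; the horizontal mark and bar are the mean ± SD. Lgals3bp is lower with ND-Exos (380 ± 113 CPM) than in BCAS (1303 ± 526) and with WD-Exos (1719 ± 831), and Gm20594 is higher with ND-Exos (694 ± 138 CPM) than in BCAS (300 ± 38.8).

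WD-Exos against BCAS asks the same of the WD kind. Oxidative phosphorylation genes fell as a list with WD-Exos (55 of 74 lower, median log2 fold change -0.14, camera adjusted p = 0.000479; adjusted p = 0.86 with an estimated correlation; 0 past adjusted over the list alone or over all genes). Cox6b1, a subunit of cytochrome c oxidase, stood at 275 ± 54.4 CPM with WD-Exos and 371 ± 43.5 in BCAS (log2 fold change -0.43, SE 0.14, adjusted p = 0.816). Ribosomal proteins were lower as a list (66 of 81 lower, median -0.10, camera adjusted p = 0.000479, and adjusted p = 0.86 with an estimated correlation). In this list 0 members passed adjusted over the list alone or over all genes. When these libraries were regrouped in 100 splits, the real one included, 34 gave a camera p for this list as small. A further fall beyond BCAS therefore cannot be told from chance. Rps27 stood at 769 ± 130 against 950 ± 123 CPM and Rpl36 at 254 ± 42.1 against 314 ± 47.7 CPM, neither past the threshold (adjusted p = 1). Immediate early and heat shock genes rose (15 of 22 higher, median 0.42, camera adjusted p = 0.0335; adjusted p = 0.86 with an estimated correlation; 0 past adjusted over the list alone or over all genes). Jun stood at 701 ± 1013 against 189 ± 140 CPM and Socs3 at 143 ± 172 against 33.7 ± 38.7 CPM. Without WD-Exos replicate 2 the log2 fold change went from 1.89 to 0.68 for Jun and from 2.08 to 1.19 for Socs3.

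No gene passed the edgeR test in WD-Exos against BCAS (379 with an unadjusted p under 0.05, 511 by chance; smallest adjusted p = 0.816), whereas DESeq2 called 399 and voom 1. The lower genes with the smallest p were Commd10 (71.3 ± 17.7 against 133 ± 29.7 CPM), the actin nucleator Spire1 (18.8 ± 12.3 against 61.0 ± 19.4 CPM) and the peroxiredoxin Prdx2 (109 ± 16.2 against 177 ± 35.3 CPM), all with adjusted p = 0.816. Every WD-Exos library was below every BCAS library for Spire1 and Prdx2. The higher ones were near the limit of detection in BCAS, also with adjusted p = 0.816. Lamb2 (11.16 ± 12.03 CPM) had no count in BCAS and was 564-fold above a floor of 3 counts, which is not a lower bound with amplified reads. Dyrk1b (5.19 ± 3.89 CPM) had 2 counts in BCAS and Hdac6 (19.6 ± 24.8 CPM) had 1. BCAS was the lowest group for these genes. In Sham, Lamb2, Dyrk1b and Hdac6 stood at 6.74 ± 5.51, 3.33 ± 4.75 and 9.52 ± 10.6 CPM. With ND-Exos they stood at 4.71 ± 5.53, 1.27 ± 2.15 and 1.83 ± 3.23 CPM. Without WD-Exos replicate 2 the camera test called 0 lists (adjusted p = 0.268 for oxidative phosphorylation, 0.412 for immediate early genes and 0.132 for ribosomal proteins). Without BCAS replicate 2 it called 6, with 0.686 for ribosomal proteins, which were also lost without WD-Exos replicate 5 (0.152). The immediate early list was lost as well without BCAS replicate 3 (0.0558), 4 (0.297), 5 (0.338) or 6 (0.384) or WD-Exos replicate 1 (0.261) or 3 (0.279).

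WD-Exos against ND-Exos compares the exosome kinds directly. Lgals3bp was higher with WD-Exos, at 1719 ± 831 CPM, than with ND-Exos, at 380 ± 113 CPM (log2 fold change 2.18, SE 0.30, n = 6, adjusted p = 0.000522). Against BCAS (1303 ± 526 CPM) Lgals3bp did not pass with WD-Exos (log2 fold change 0.40, SE 0.29). Gm20594 was lower with WD-Exos, at 299 ± 80.0 CPM, than with ND-Exos, at 694 ± 138 CPM (log2 fold change -1.21, SE 0.17, adjusted p = 0.000522). In BCAS Gm20594 stood at 300 ± 38.8 CPM. For both genes the 6 libraries of one kind lay apart from the 6 of the other. Of 25 interferon response genes 23 were higher with WD-Exos than with ND-Exos (median log2 fold change 1.35, camera adjusted p = 3.02e-12, and adjusted p = 0.318 with an estimated correlation). In the list 4 passed adjusted over the list alone (0 over all genes tested). Ifi27l2a stood at 227 ± 144 against 43.8 ± 27.8 CPM (log2 fold change 2.37, SE 0.52, adjusted p = 0.254) and the tethering protein Bst2 at 253 ± 129 against 95.1 ± 29.1 CPM (1.41, SE 0.36, adjusted p = 0.299), with every WD-Exos library above every ND-Exos library for Bst2. The interferon score was 5.05 ± 1.02 with WD-Exos and 3.58 ± 0.68 with ND-Exos (exact permutation p = 0.0173, adjusted p = 0.169). The difference was 1.12 among replicate numbers 1 to 3 and 1.83 among numbers 4 to 6. Inflammatory cytokines and NF-kB targets were higher with WD-Exos than with ND-Exos (17 of 19 higher, median 0.79, camera adjusted p = 0.0266, and adjusted p = 0.72 with an estimated correlation). In that list 0 members passed adjusted over the list alone or over all genes. The adhesion molecule Icam1 stood at 200 ± 61.6 against 117 ± 64.1 CPM and Tnfaip3 at 63.9 ± 71.6 against 7.35 ± 8.44 CPM (log2 fold change 3.12, and 2.30 without WD-Exos replicate 2). The NF-kB score was 5.642, 6.696 and 5.608 in WD-Exos replicates 1 to 3 and 4.274, 4.913 and 4.301 in replicates 4 to 6, against 4.41 ± 0.56 with ND-Exos (exact permutation p = 0.0909, adjusted p = 0.552). WD-Exos replicates 1 to 3 also had the highest immediate early scores of the group (7.973, 8.852 and 8.015, against 5.247 to 6.674 in replicates 4 to 6). Of 22 immediate early and heat shock genes 19 were higher with WD-Exos than with ND-Exos (median 1.13), which did not pass (camera adjusted p = 0.502).

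Of the metabolic lists, oxidative phosphorylation alone passed the camera test between the exosome kinds. Its genes fell with WD-Exos (58 of 74 lower, median log2 fold change -0.24, camera adjusted p = 9.66e-05; adjusted p = 0.72 with an estimated correlation; 0 past adjusted over the list alone or over all genes). It did not pass by fry (adjusted p = 0.326), and the score was 6.72 ± 0.20 against 6.89 ± 0.11 (exact permutation p = 0.106, adjusted p = 0.552). The complex I genes Ndufv3 (63.1 ± 14.4 against 94.3 ± 7.54 CPM) and Ndufc2 (96.9 ± 7.45 against 140 ± 19.5 CPM) were lower in every WD-Exos library than in any ND-Exos library, with adjusted p of 0.594 and 0.63. Of 21 glycolysis genes 13 were higher with WD-Exos (median 0.19), which did not pass (camera adjusted p = 0.0637). The glycolysis score was 6.85 ± 0.30 against 6.34 ± 0.13 (exact permutation p = 0.00433, adjusted p = 0.113). The other metabolic lists were also not past the threshold: tricarboxylic acid cycle and fatty acid oxidation (adjusted p = 0.947 each), cholesterol synthesis (0.922), cholesterol efflux (0.558), lipid uptake and droplets (0.947), fatty acid synthesis (0.908), NRF2 targets (0.259) and lysosome (0.0779). For the tricarboxylic acid cycle, fatty acid oxidation, cholesterol synthesis, lipid uptake and fatty acid synthesis lists, the median, the mean and the test did not share a sign. In the lysosome list 2 genes passed adjusted over the list alone (0 over all genes), one of them the progranulin gene Grn (3425 ± 446 against 2015 ± 448 CPM, log2 fold change 0.77, SE 0.16, adjusted p = 0.254 over all genes).

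Among other genes with small p in WD-Exos against ND-Exos, Ncf1 was higher with WD-Exos (578 ± 140 against 289 ± 130 CPM, adjusted p = 0.29). Lower were glutathione peroxidase Gpx1 (696 ± 93.7 against 954 ± 143 CPM), Dock10 (70.2 ± 26.5 against 182 ± 59.7 CPM) and Zfhx3 (106 ± 19.9 against 183 ± 35.1 CPM), each with adjusted p = 0.299. Altogether 545 genes had an unadjusted p under 0.05 (511 by chance), and DESeq2 called 454. The summed CPM of border macrophage markers was 245 ± 69.5 with WD-Exos and 493 ± 286 with ND-Exos (exact permutation p = 0.0173, adjusted p = 0.331). Gene counts ranged from 2 to 5 when libraries were left out, the 5 without ND-Exos replicate 5. The number of lists was 5 without ND-Exos replicate 1 or 6 or WD-Exos replicate 5. The NF-kB list had an adjusted p of 0.2 without ND-Exos replicate 3 and 0.0535, 0.16 and 0.0619 without WD-Exos replicates 1, 2 and 3, and the oxidative phosphorylation list one of 0.0517 without WD-Exos replicate 2. In a fit of these 12 libraries alone, 1 gene passed, Lgals3bp, and Gm20594 had an adjusted p of 0.0786.

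**Figure D2:**
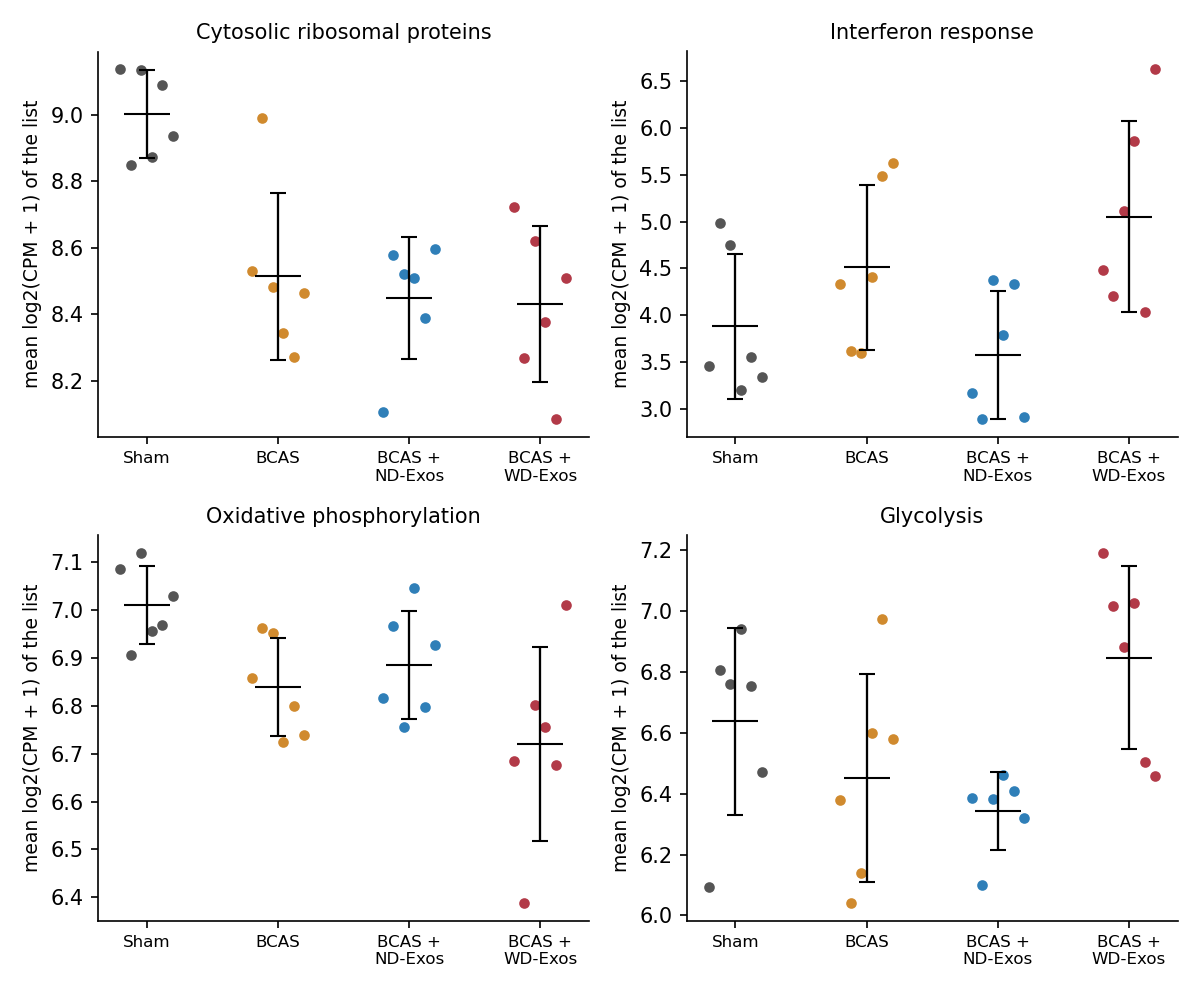
Score of 4 gene lists, the mean log2(CPM + 1) of the tested members (vertical axis, log2 scale, not starting at 0), for each of the 24 libraries; points are libraries, marks and bars mean ± SD of 6. Ribosomal proteins are lower in BCAS (8.51 ± 0.25) than in Sham (9.003 ± 0.133), and the interferon score is higher with WD-Exos (5.05 ± 1.02) than with ND-Exos (3.58 ± 0.68).

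Libraries also differed in transcripts of other cells. The summed CPM of oligodendrocyte markers was 14073 in Sham replicate 4, 9622 in ND-Exos replicate 3 and 9974 in WD-Exos replicate 6, against 1607 to 5980 in the other libraries. By group it was 5984 ± 3990 in Sham, 4399 ± 1500 in BCAS, 5105 ± 2230 with ND-Exos and 5583 ± 2200 with WD-Exos, and no comparison of it had an exact permutation p under 0.403. Without those 3 libraries, a choice made after seeing the data, the number of genes past the threshold was 0 in BCAS against Sham, 1 in ND-Exos against BCAS, 0 in WD-Exos against BCAS and 2 in WD-Exos against ND-Exos, and the number of lists was 8, 2, 5 and 3. None of the 68 tests of library measures passed after adjustment, and 5 had an exact permutation p under 0.05. With a smallest possible p of 0.00216, a single measure could not pass over 68 tests. The absence of calls therefore does not show that the groups were alike.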

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

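Of the tests in this part, the length-matched comparison of ribosomal proteins was written down before its result was seen, and it was then repeated with transcript lengths after a first run had used gene spans (difference -0.482 with transcript lengths). The other tests of explanations and the counts of splits were chosen after the results were seen.

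A library that stood apart from the other 5 of its group was found in 39 of 303 groups of values (12.9%). The bound used gives about 5% by chance only for normally distributed values. Many values here are not, some lie near the limit of detection, and several items overlap. The 12.9% therefore cannot be set against 5%. BCAS replicate 2 was the highest of its group for the ribosomal protein share (5.78%, the others 3.66 to 4.12%) and score (8.99), and for Rplp1 (1370 CPM), Rps24 (651 CPM), Rps28 (490 CPM) and Atf3 (1840 CPM). WD-Exos replicate 2 was the highest of its group for Jun (2700 CPM), Socs3 (472 CPM) and Tnfaip3 (202 CPM).

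Summed oligodendrocyte markers were 14100 CPM in Sham replicate 4, 9620 CPM in ND-Exos replicate 3 and 9970 CPM in WD-Exos replicate 6. The same 3 libraries led their groups in ependymal and choroid plexus markers, with 462, 410 and 294 CPM. ND-Exos replicate 3 also stood apart in genes with a count (10600), oligodendrocyte precursor markers (85.8 CPM), neuron markers (85 CPM) and a low homeostatic score (10.6). Sham replicate 1 stood apart in oligodendrocyte precursor markers (58.7 CPM), neuron markers (349 CPM), erythroid markers (2.12 CPM) and Dyrk1b (12.7 CPM). Single high values of other cell types were 1.8 CPM of oligodendrocyte precursor markers in BCAS replicate 6, 391 CPM of astrocyte markers in WD-Exos replicate 4, 1570 CPM of endothelial markers in Sham replicate 3 and 1030 CPM of mural markers in Sham replicate 2. Erythroid markers reached 4.16 CPM in BCAS replicate 3 and 13.2 CPM in WD-Exos replicate 2.

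Single genes with 1 library apart were Ifit3 in BCAS replicate 6 (235 CPM), Nfe2l2 in BCAS replicate 6 (404 CPM), Nfkbiz in Sham replicate 2 (7.75 CPM), Ncf1 in Sham replicate 5 (586 CPM) and Cox5a in WD-Exos replicate 6 (135 CPM). Near the limit of detection these were Il6 in ND-Exos replicate 2 (5.27 CPM), Cd163 in WD-Exos replicate 5 (13.2 CPM), Eme2 in Sham replicate 6 (0.33 CPM), and Hdac6 in BCAS replicate 1 (0.04 CPM) and ND-Exos replicate 1 (7.97 CPM).

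The lower level of ribosomal protein transcripts in BCAS than in Sham (score difference -0.49) was weighed first. Against genes matched on transcript length and mean CPM the difference was -0.482 (SE 0.146, exact permutation p = 0.013, 80 of 81 members), which argues against a length or abundance trend as the whole cause. With the number of detected genes as a covariate it was -0.407 (SE 0.123), which argues against detection as the whole cause. With the immediate early level of each library it was -0.528 (SE 0.112). The mean of that level did not differ clearly between BCAS and Sham. This argues against stress during sorting as the whole cause only as far as these genes mark it. An unrecorded difference in preparation and an effect of the operation both stay open, and the latter may be kept only as a hypothesis. In the splits of the 12 libraries, 1 of 100, the real one itself, gave a camera p for this list that small. The smallest camera p of another split was 3.39e-35, and these shares are not adjusted over lists or comparisons.

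The higher interferon response with WD-Exos than with ND-Exos (score difference 1.48) was weighed next. Members with a mean of at least 50 CPM in the Sham and BCAS libraries, which are outside this comparison, differed by 1.57 (SE 0.482, exact permutation p = 0.00866, 10 members), which argues against dropouts of low genes as the whole cause. With the immediate early level as a covariate the difference was 1.67 (SE 0.382). This argues against stress during sorting as the whole cause only as far as these genes mark it. A difference in preparation between the groups was not tested, and an effect of the exosomes may be kept only as a hypothesis. The list's camera p was as small in 4 of 100 splits, the real one included. It was also 4 of 100 for ND-Exos against BCAS, 8 of 100 for BCAS against Sham and 65 of 100 for WD-Exos against BCAS. In each comparison another split gave a smaller camera p than the real one. For WD-Exos against ND-Exos it was 1.44e-18 (real 1.16e-13), and for ND-Exos against BCAS 9.92e-13 (real 2.59e-10). For BCAS against Sham it was 5.74e-08 (real 6.24e-06), and for WD-Exos against BCAS 6.91e-17 (real 0.103, so the list did not pass there). These shares are not adjusted over lists or comparisons, so chance cannot be excluded in any of them.

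The higher Gm20594 with ND-Exos was weighed last. Its transcript of 449 bases aligned to the mitochondrial 16S ribosomal RNA over 435 bases with 88.5% identity and a longest identical stretch of 65 bases, so reads of that RNA are a candidate source of its counts. Mitochondrially encoded genes are not analysed here, so a change in Gm20594 itself stays open too.

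For the number of genes changed, the part played by chance was examined with 100 splits in each comparison, the real one included. In WD-Exos against ND-Exos the real split alone called as many as 2 genes (1 of 100, highest other 1). The splits are a sample of those possible, and this share is not adjusted over the comparisons. Gm20594, whose counts are uncertain, was among these genes, so chance is made less likely there but is not excluded. In ND-Exos against BCAS 4 of 100 splits called 2 genes or more, the real one included, and the highest other called 16. That share is also not adjusted over the comparisons, and the real count lies within the range of the other splits, so chance cannot be excluded there. In BCAS against Sham and WD-Exos against BCAS the real count was 0, so 100 of 100 splits gave as many (highest other 1 and 22). The split of the BCAS and WD-Exos libraries with 22 genes was that of replicate numbers 1 to 3 against 4 to 6, which points to a structure of the samples along these numbers. Of 9 splits there with 5 of the 6 libraries of numbers 1 to 3 on one side, 2 called genes (highest 13) and 7 called 0, and in BCAS against Sham the split by these numbers called 0. Over all 24 libraries the numbers differed in 12 lists and 0 genes, and the interferon difference, BCAS minus Sham, was -0.545 in numbers 1 to 3 and 1.81 in numbers 4 to 6. With these numbers as a covariate WD-Exos against BCAS again gave 0 genes. The split with 16 genes in ND-Exos against BCAS had 2 libraries of numbers 1 to 3 on one side and 4 on the other, and what lies behind it stays open. For the number of lists chance cannot be excluded in any comparison: 8 in BCAS against Sham (18 of 100, highest other 12), 2 in ND-Exos against BCAS (82 of 100, highest other 10), 3 in WD-Exos against BCAS (72 of 100, highest other 12) and 3 in WD-Exos against ND-Exos (68 of 100, highest other 9). The other splits called a median of 4 lists in each comparison, more than the real split in every comparison of an exosome group.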

How the results depend on the processing

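The filter of 10 counts in all 24 libraries, the omission of 3 libraries, the covariates of replicate numbers and of immediate early level, and the permutation of scores were chosen after seeing the data. Counts below are in the order BCAS against Sham, ND-Exos against BCAS, WD-Exos against BCAS, WD-Exos against ND-Exos. RLE factors, no filter, 10 counts in 12 libraries and the replicate numbers as covariate left 0, 2, 0 and 2 genes, as in the results above.

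The replicate numbers did not pair the samples: same-number deviations correlated from -0.0844 to 0.129, and 0, 1, 1 and 0 of 6 libraries matched their own number best. With the replicate number as a block, 0, 2, 0 and 2 genes and 7, 2, 3 and 3 lists passed; the block ended 1 call, immediate early genes in BCAS against Sham (adjusted p = 0.0507).

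Detected genes as a covariate gave 1 gene in ND-Exos against BCAS, without Lgals3bp, and 5, 4, 3 and 4 lists, of which 5, 2, 1 and 2 were among the 8, 2, 3 and 3 called without it. It ended the calls of homeostatic genes (adjusted p = 0.472), antigen presentation and border macrophages (0.168 each) in BCAS against Sham, of oxidative phosphorylation (0.0855) and immediate early genes (0.822) in WD-Exos against BCAS, and of NF-kB targets (0.0892) in WD-Exos against ND-Exos. NF-kB targets were also lost there without a filter (0.0561), with 10 counts in 12 libraries (0.0575) or in all 24 (0.185) and with the immediate early level (0.126). Immediate early genes in WD-Exos against BCAS were also lost without a filter (0.208), with 10 counts in 12 libraries (0.053) and with 2 groups (0.196). In BCAS against Sham, voom ended immediate early genes (0.189) and border macrophages (0.142), replicate numbers 1 to 3 against 4 to 6 ended immediate early genes (0.0566), and omission of 3 libraries ended antigen presentation (0.0703). The immediate early level ended NF-kB targets (0.0715), oxidative phosphorylation (0.0519) and border macrophages (0.109) there. A fit of 2 groups gave 1 gene in WD-Exos against ND-Exos. At least 10 counts in all 24 libraries, a filter that can remove genes that fell, gave 6 genes in BCAS against Sham and 0 lists in WD-Exos against BCAS. The immediate early level as a covariate gave 14 genes and 4 lists in BCAS against Sham and 5 genes in WD-Exos against ND-Exos; its own list stayed among the 26 tested, but its value is not given because it defines the covariate. Voom gave 9, 1, 1 and 4 genes, without Lgals3bp in ND-Exos against BCAS. DESeq2 gave 593, 481, 399 and 454, of which 397, 379, 329 and 338 had a log2 fold change beyond 10 in size; 376, 365, 313 and 326 of these had no count in 1 of the groups compared. Without the 3 oligodendrocyte-rich libraries 1 gene passed in ND-Exos against BCAS, not Lgals3bp, and 5 lists in WD-Exos against BCAS. An estimated correlation and exact permutation of scores left 0 lists in each comparison, and fry 1, 0, 0 and 0. A single list could not pass that permutation over 26 lists, because its smallest possible p is 0.00216. Why the estimated correlation and fry left so few lists was not tested directly. At the preset correlation, camera called a median of 4 lists in the other splits of the libraries of each comparison. In the simulations, where genes varied independently, it called 0.667 lists besides glycolysis, which was changed in them. The preset correlation thus gave calls without the real grouping. Leaving out 1 library at a time gave 0 to 32, 1 to 3, 0 to 0 and 2 to 5 genes and 5 to 11, 2 to 5, 0 to 6 and 2 to 5 lists, and 0 library measures throughout.

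Fold changes near 0 of genes given as levels changed sign, with an adjusted p of 1 or, with voom, 0.997 and 0.995. These values had been set aside after their sign changes were seen and were then restored. Gm20594 in WD-Exos against BCAS was 0.0067 with RLE, 0.01004 without a filter, 0.0043 with 10 counts in 12 libraries, 0.11 with detected genes, 0.01005 with 2 groups, 0.02959 with 10 counts in all 24, 0.066 with the immediate early level and 0.0068 with DESeq2. Cx3cr1 was 0.065, 0.068 and 0.019 in ND-Exos against BCAS (detected genes, 3 libraries removed, immediate early level), -0.065 and -0.0040 in WD-Exos against ND-Exos (3 libraries removed, voom) and -0.0046 in WD-Exos against BCAS (voom). With detected genes, P2ry12 was 0.052 in WD-Exos against BCAS. With 1 library left out, Cx3cr1 ranged from -0.131 to 0.08003 in ND-Exos against BCAS, from -0.05755 to 0.1212 in WD-Exos against BCAS and from -0.04319 to 0.1412 in WD-Exos against ND-Exos. Gm20594 ranged from -0.08425 to 0.1027 in WD-Exos against BCAS. Of the genes tested, 52% had a library without a count.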

Other observations

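The comparisons of scores against Sham, the split by replicate number and the difference of 2 scores in this part were chosen after the results were seen; the simulated values for shared libraries were computed after them too.

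Both exosome groups also lay below Sham in ribosomal protein transcripts. The score was 8.45 ± 0.18 with ND-Exos and 8.43 ± 0.24 with WD-Exos against 9.003 ± 0.133 in Sham (differences -0.554 and -0.573, exact permutation p = 0.00216 for both, the smallest these permutations can give; adjusted p = 0.0281 and 0.0563), with 6 of 6 libraries below every Sham library in each. These comparisons share the Sham libraries. Immediate early and heat shock genes were higher with ND-Exos than in Sham (6.66 ± 0.26 against 5.66 ± 0.43, exact permutation p = 0.00216, adjusted p = 0.0281). The score of NRF2 antioxidant targets was 5.73 ± 0.22 in BCAS and 6.08 ± 0.11 in Sham (exact permutation p = 0.00866, adjusted p = 0.113). Disease-associated microglial genes did not pass in any comparison (camera adjusted p = 0.655, 0.978, 0.955 and 0.947). Gm20594 stood at 300 ± 38.8 CPM in BCAS and 409 ± 41.5 in Sham, lower in 6 of 6 libraries, but did not pass (adjusted p = 0.441).

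By camera the interferon list was higher in BCAS than in Sham and lower with ND-Exos than in BCAS, but neither passed with an estimated correlation (adjusted p = 0.34 and 0.473). Both comparisons use the BCAS libraries, and BCAS minus Sham was -0.545 in replicate numbers 1 to 3. The score with ND-Exos against Sham differed by -0.303 (exact permutation p = 0.487). Across the 1423 genes above 100 CPM, which are not independent replicates, the fold changes of these comparisons correlated with r = -0.187, against a median of -0.499 (range -0.799 to -0.0479) in simulations without effects; the covariance was -0.0253 against -0.0499, a difference of 0.0245. With the BCAS libraries split between the comparisons the mean r was 0.187. For BCAS against Sham and WD-Exos against BCAS the values were -0.235, -0.506 and 0.181, with a covariance difference of 0.0221. ND-Exos and WD-Exos, each against BCAS, gave r = 0.244, 0.496 simulated and -0.219 with split controls, and a covariance difference of -0.0251.

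Replicate numbers 1 to 3 and 4 to 6 differed in 12 of 26 lists and 0 genes (edgeR, 498 with an unadjusted p under 0.05), led by lower immediate early genes and higher homeostatic genes in numbers 4 to 6 (camera adjusted p = 2.79e-10 and 1.88e-07). As many lists were called in 2 of 100 splits balanced over the groups. The labels name no batch.

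A hypothesis formed after the scores of 26 lists in 6 comparisons had been seen is that oxidative phosphorylation may be lower relative to glycolysis in microglia with WD-Exos. The oxidative phosphorylation score minus the glycolysis score was -0.127 ± 0.441 with WD-Exos and 0.542 ± 0.188 with ND-Exos, a difference of -0.669 (SE 0.196, exact permutation p = 0.00866, not adjusted). Against BCAS (0.387 ± 0.427) the WD-Exos difference had an exact permutation p of 0.0714, ND-Exos against BCAS had 0.446, and BCAS against Sham (0.374 ± 0.359) had 0.957. The test was run on the data that gave the hypothesis, and transcripts do not measure metabolic rates.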
